A study of Mus musculus with 29 samples.

How the data were processed

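Gene expression had been measured on 29 mouse Affymetrix arrays, 1 per sample, in 5 groups. The normal groups were pro-B cells (2 arrays; B220+ CD43+ IgM- bone marrow cells) and mature B cells (4 arrays; B220+ spleen cells), each sorted from normal mice. Of the 23 tumour arrays, 6 came from pro-B lymphomas lacking Lig4 and p53 with amplified c-myc (LPC), 11 from lymphomas lacking Artemis and p53 with amplified c-myc (APC) and 6 from lymphomas lacking Artemis and p53 with amplified N-myc (APN). Per the labels, tumour tissue was taken from foci in the cervical lymph node or the thymus and kept in RNA preservative, sorting for RNA was described for the normal cells, RNA was extracted with Trizol, and the one-cycle biotin protocol was used. The labels call the arrays of a group biological replicates. Site, sex and scan date of each sample, and the position of each probe set in its transcript, were not given in the sources used here. Read from the values, Xist, a sex-linked gene, was at least 1500 on 2 of 2 pro-B and 2 of 4 mature B arrays. Among tumours it was so on 2 of 6 LPC, 3 of 11 APC and 5 of 6 APN arrays. The groups compared were thus uneven in Xist. On APC 6, 1 of these arrays (1575), the Y-linked Eif2s3y also read 2781, so this is a rough mark of sex.

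The deposited table held 1 intensity per probe set and array, on the linear scale, made by the authors with MAS5 per the submitters' processing notes. The version, the background settings and the detection calls of MAS5 were not given in the sources used here. Read from the values, the 2% trimmed mean was 500 on every one of the 29 arrays, so the deposited intensities were taken as scaled between arrays and were used as they were, as log2 values without an offset. No column was a copy of another: over all probe sets but the controls, the highest pairwise correlation of log2 signals was 0.948 and the lowest 0.820. Of 45101 probe sets, 64 controls were left out. The remaining 45037 were named from the gene annotation in the box: 34945 had 1 gene symbol, 932 had several and 9160 had none, and the last 2 kinds were not tested as genes. Trp53 and Dclre1c (Artemis) had no probe set under those names and were not analysed here.

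A probe set was kept when its signal lay above the median of its own array on at least 2 arrays. That kept 29214 probe sets, 24302 of them with 1 gene symbol, for 12927 genes. Each gene was represented by its probe set with the highest mean log2 signal. All 29 arrays went into 1 linear model with the 5 groups (limma 3.58.1 in R 4.3.3, lmFit and eBayes with an intensity trend), and p-values were adjusted by the Benjamini-Hochberg method within each of 9 comparisons, with calls at an adjusted p under 0.05. The value for the tumours was the mean of the LPC, APC and APN means with equal weights. Errors after a plus-minus sign are standard errors of the model for differences and standard deviations for group means. Median signals of the arrays are given in the report in place of read depth.

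Unequal change between probe sets was tested for 6324 genes with at least 2 kept probe sets (limma diffSplice, F test). A gene was called unequal at an adjusted p under 0.05 when its probe sets' log2 differences spanned at least 1. It was called opposite when 1 of its probe sets rose and another fell, each at an adjusted p under 0.05.

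The 27 gene lists, written by hand, were tested with limma camera (preset correlation 0.01, smallest list 5 measured genes), again with the correlation estimated for each list, and with fry. For each list the number of members that rose or fell is given, with the number that passed when p-values were adjusted over the list alone. Btg2, Bax and Ldha each stood in 2 lists.

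Genes were named by a rule: adjusted p under 0.05, at least 2-fold, groups that did not overlap, and the brighter group's mean above the mean array median. Predicted genes, immunoglobulin and T cell receptor segments, Xist and Y-linked genes were left out. Up to 10 genes each way were taken in order of size for tumours against pro-B, mature B against pro-B and the tumour types against each other, and up to 5 elsewhere. The condition on overlap was dropped for a side with fewer than 3 genes, which applied to LPC against APC and to the genes lower in APC than in APN. Up to 4 called members each way were named for a list, and the 8 genes with the smallest p for unequal change. Lig4, Myc and Mycn were always named. Where every array of the dimmer group lay below its own median, the fold was computed against that median and is given as "at least". No fold is given where only some of its arrays did so and its median signal lay below or near the array medians. List medians are also given with genes wholly below at that bound.

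Tested on simulated data, with 100 genes put in per size, a log2 change of 1 was found for 45% of genes in tumours against pro-B, 65% in tumours against mature B, 30% in mature B against pro-B, 58% in LPC against APC, 69% in APC against APN and 54% in LPC against APN. A log2 change of 2 was found for 80%, 86%, 69%, 90%, 92% and 84%. Unequal change of log2 2, put into 200 genes, was found for 74%, 83%, 60%, 87.5%, 87.5% and 82%. In the simulated data genes varied independently, and far fewer genes changed than were called in the comparisons with normal cells. The rates therefore do not give the power of those comparisons.

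The groups, comparisons, lists, thresholds and the following alternatives were chosen before the data were examined: quantile normalization, a common 75th percentile, no filter, a filter at the 75th percentile, an offset of the 20th percentile of all signals (12.5), no intensity trend, only the groups compared, array weights, a Gapdh 3'-to-5' covariate, the replicate number as a block, leaving out each array, the mean of a gene's probe sets, all probe sets 1 by 1, an adjusted p under 0.01, unequal change without probe sets of the _s, _x and _a kinds or without a minimum difference, the estimated list correlation and fry. The Xist covariate, leaving out LPC 1 and LPC 2 together and, for unequal change, raising each signal below the median of its array to that median were chosen after the data had been seen, as were lists of salivary gland and skeletal muscle genes. Random splits of the arrays (100 per comparison, seed 20240) mixed groups with at least 3 arrays on each side.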

Results

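The 3 lymphoma types were compared with normal pro-B and mature B cells and with each other. The amplified oncogenes came first, then genes, gene lists and unequal change between the probe sets of a gene. Tumour RNA came from tissue, and sorting was described for the normal cells only. Handling and the content of other cells therefore cannot be told apart from tumour status where tumours are compared with normal cells.

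Myc and Mycn encode related transcription factors that drive cell growth, and each was high in the tumours whose group name carries it. The Myc signal had a median of 13259 (10103 to 18069) in 6 LPC and 14255 (11826 to 15900) in 11 APC arrays, against 252 (36 to 1724) in 6 APN, 1981 in 2 pro-B and 1624 in 4 mature B arrays. On the log2 scale Myc rose over pro-B by 2.73 ± 0.73 in LPC (6.64-fold, adjusted p = 0.00431) and by 2.81 ± 0.69 in APC (7.02-fold, adjusted p = 0.00163). In APN Myc lay below pro-B, with a log2 difference of -3.21 ± 0.73 (9.24-fold, adjusted p = 0.00101). The signal of the brightest Mycn probe set had a median of 25953 (22445 to 30825) in APN, 463 (5 to 12002) in APC, 52 (4 to 730) in LPC, 198 in pro-B and 17 in mature B. Mycn rose in APN over pro-B by 7.05 ± 1.88 (133-fold, adjusted p = 0.00411). Among the APC arrays, APC 2 read 12002 for Mycn, APC 1 2146 and APC 6 1577. Of the other 2 probe sets of Mycn, 1 had medians of 5831 in APN, 87 in APC and 48 in LPC. The last was flat, with medians of 54 to 58 in the 3 tumour types. Lig4, which encodes the ligase of non-homologous end joining and is the gene disrupted in LPC, read 581 (424 to 817) in LPC, 728 in APC, 898 in APN, 1727 in pro-B and 319 in mature B. LPC against APC gave -0.26 ± 0.19 for Lig4 (adjusted p = 0.517). Where this probe set lies relative to the deletion was not given.

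**Figure D1:**
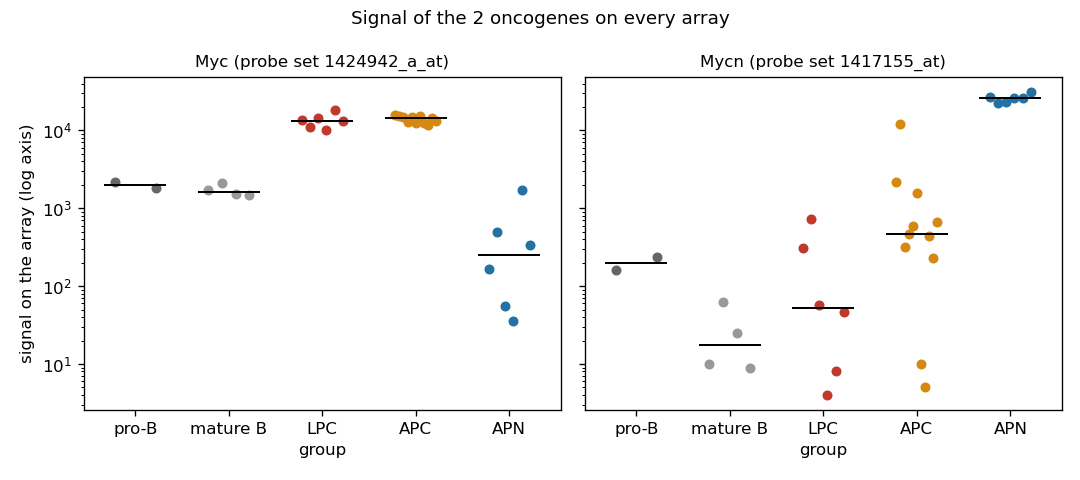
Signals of Myc and Mycn on each of the 29 arrays by group.

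Among the genes named for tumours against pro-B cells were several of connective tissue, high in the tumours, and several of early B cells, granulocytes and other bone marrow cells, high in pro-B. Col3a1, a fibrillar collagen of connective tissue, rose by 8.05 ± 0.68 log2 (medians 4460 in 23 tumours and 16.1 in 2 pro-B arrays, at least 64.3-fold, adjusted p = 3.7e-10). Dntt, the polymerase that adds nucleotides at the joints of rearranging antibody genes, changed by -10.43 ± 0.83 (medians 12.1 and 16000, at least 186-fold lower, adjusted p = 1.4e-10). Cdkn2a, which encodes the tumour suppressors p16 and p19Arf, rose by 7.80 ± 0.76 (medians 1580 and 7.36, at least 21.5-fold, adjusted p = 4.6e-09). In all, 5157 of 12927 genes changed, 2563 higher and 2594 lower in tumours, and 1369 and 1403 of them by at least 2-fold.

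Other genes high in the tumours were Fstl1, a secreted glycoprotein of mesenchymal cells (medians 1730 and 5.07, at least 25.8-fold), the actin-binding Cald1 (9.48 ± 0.67, at least 14.3-fold), and the pericyte gene Rgs5 (7.86 ± 0.57, medians 2400 and 11.5, at least 34.5-fold). So were Pcolce (at least 7.11-fold), Sparcl1 (at least 8.99-fold), Tm4sf1 (at least 5.27-fold), Abcc9 (at least 7.03-fold) and Tmem204 (at least 1.99-fold). Lower in the tumours were the chemokine receptor Ccr9 (-8.87 ± 0.98, medians 23.5 and 9160), Siglech, a receptor of plasmacytoid dendritic cells (-8.75 ± 0.91, 21.8 and 8230), and Camp, an antimicrobial peptide of granulocytes (-7.88 ± 1.11, 14.6 and 5450). Lower too were the lymphoid surface protein Cd7 (-7.67 ± 0.55, at least 40.2-fold), Klra17 (at least 34.4-fold), Myl10, Smim5, Klk1b27 and D13Ertd608e. Without pro-B 1 the count of changed genes was 2754 and without pro-B 2 it was 2839, with a single pro-B array left that was taken to vary like the other groups.

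Genes of ribosome biogenesis and growth, many of them bound by Myc, rose in the tumours. Of 37 measured, 34 rose and 0 fell by the limma test (36 passed with p-values adjusted over the list alone). The median log2 difference was 0.98, and the list passed with both correlations (adjusted p = 6.2e-19, and adjusted p = 0.0188 with an estimated correlation). Gnl3, a nucleolar protein of growing cells, rose by 1.84 ± 0.17 (3.57-fold, medians 10100 and 2700). The RNA polymerase I subunit Polr1a rose by 1.85 ± 0.22, and the ribosome assembly factors Utp20 and Wdr12 by 1.84 ± 0.17 and 1.77 ± 0.15. Ribosomal protein genes rose for 12 of 16 and fell for 1 (14 over the list alone, median 0.41, adjusted p = 0.00197, and adjusted p = 0.405 with an estimated correlation). This call was lost after quantile normalization (median 0.01, adjusted p = 0.952). Rps6 was the member that fell (-0.84 ± 0.24).

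Pro-B and pre-B cell genes fell in the tumours for 15 of 17 members (17 over the list alone, median -2.28, adjusted p = 3.5e-09, and adjusted p = 0.0188 with an estimated correlation). After Dntt these were led by the surrogate light chain genes Vpreb1 (-7.22 ± 1.28) and Igll1 (-6.67 ± 1.00, 102-fold, medians 156 and 18700) and by Erg (-6.25 ± 0.59). B lineage identity genes fell for 10 of 15 and rose for 2 (12 over the list alone, median -0.82, adjusted p = 0.0258, and adjusted p = 0.405 with an estimated correlation). Irf8, a transcription factor of B and myeloid cells, changed by -2.30 ± 0.16 and Ebf1 by -1.14 ± 0.22, while Ikzf3 rose by 1.63 ± 0.34 and Pax5 by 1.31 ± 0.39. Mature B cell genes were not passed (4 of 24 rose, 5 fell, 9 over the list alone, median -0.30, or -0.08 with 2 members at their bound, adjusted p = 0.916). Neither were germinal centre and plasma cell genes (1 of 11 rose, 6 fell, median -1.32, or -0.28 with 3 at their bound, adjusted p = 0.0743).

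Markers of other cells stood beside these differences. Neutrophil and granulocyte precursor markers fell in all 14 members (median -5.95, or -5.80 with 3 members at their bound, adjusted p = 1.9e-09, and adjusted p = 0.0123 with an estimated correlation). S100a9, an abundant granulocyte protein, changed by -6.85 ± 0.76 (medians 115 and 17800). NK and dendritic cell markers fell in all 8 (median -4.78, or -4.42 with 1 at its bound, adjusted p = 4.2e-08, and adjusted p = 0.0123 with an estimated correlation). T cell markers fell in 12 of 15 (12 over the list alone, median -3.45, or -1.93 with 5 at their bound, adjusted p = 1.7e-05, and adjusted p = 0.00141 with an estimated correlation, Cd3d at least 6.91-fold lower). Erythroid markers were not passed (0 of 5 rose, 4 fell, adjusted p = 0.0562). In the other direction, fibroblast and stromal markers rose in all 15 (median 4.33, or 2.85 with 10 at their bound, adjusted p = 1.1e-10, and adjusted p = 0.108 with an estimated correlation). Macrophage and monocyte markers rose for 11 of 18 and fell for 3 (14 over the list alone, median 2.02, or 1.70 with 2 at their bound, adjusted p = 2.4e-04, and adjusted p = 0.344 with an estimated correlation). The complement gene C1qb rose by 4.72 ± 0.32 (26.3-fold, medians 3030 and 115), and Mpeg1 changed by -2.52 ± 0.25. Endothelial markers rose for 7 of 13 and fell for 3 (11 over the list alone, median 1.61, or 0.22 with 4 at their bound, adjusted p = 0.0279, and adjusted p = 0.344 with an estimated correlation). The mean Gapdh 3'-to-5' log2 difference was -0.45 in pro-B, -0.57 in mature B, -0.36 in LPC, -0.35 in APC and -0.39 in APN, and the same measure for actin was 0.32, 0.45, 0.56, 0.54 and 0.52. The median signals of the arrays were 65.4 to 66.3 in pro-B, 80 to 100.5 in mature B, 81.6 to 113.3 in LPC, 68.8 to 97.5 in APC and 69.6 to 93.4 in APN.

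**Figure D2:**
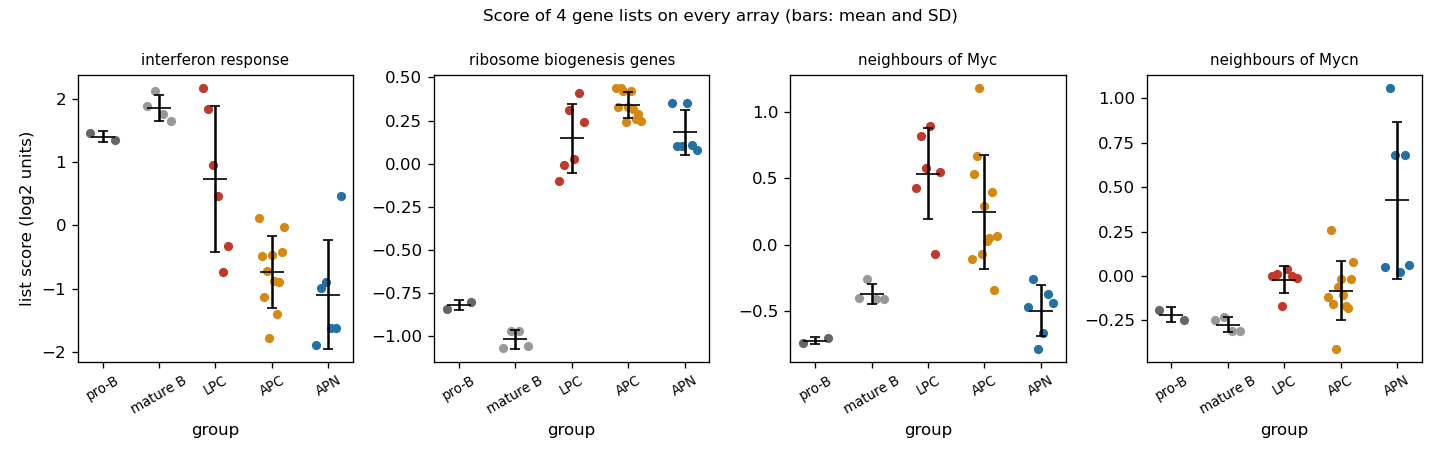
Scores on each array by group for the lists of interferon response, ribosome biogenesis, neighbours of Myc and neighbours of Mycn, with group mean and standard deviation.

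Immediate early and heat shock genes, which respond within minutes to signals and stress, fell in the tumours for 14 of 21 and rose for none (14 over the list alone, limma, median -1.80, adjusted p = 1.6e-06, and adjusted p = 0.0893 with an estimated correlation). Fos changed by -5.96 ± 0.82 (62.1-fold, medians 189 and 11300) and Jun by -5.09 ± 0.67. Sorting was described for the normal cells only, so a rise in sorted cells cannot be told apart from a fall in tumours. Interferon response genes fell for 10 of 18 (12 over the list alone, median -1.63, adjusted p = 2.4e-04, and adjusted p = 0.375 with an estimated correlation). Among them Irf7, a regulator of the interferon response, changed by -3.56 ± 0.51 (adjusted p = 2.8e-06). Genes that p53 switches on fell for 10 of 24 and rose for 1 (12 over the list alone, median -0.49, adjusted p = 0.0082, and adjusted p = 0.122 with an estimated correlation). Cdkn1a, an inhibitor of the cell cycle, changed by -2.67 ± 0.34 (medians 89 and 640, adjusted p = 5.5e-07) and Gadd45a by -1.79 ± 0.26, while Aen rose by 0.63 ± 0.15. Apoptosis regulators fell for 8 of 17 and rose for 2 (10 over the list alone, median -0.69, adjusted p = 0.025, and adjusted p = 0.06 with an estimated correlation). The caspase inhibitor Cflar stood at -1.64 ± 0.19 and the survival gene Bcl2l1 at -1.22 ± 0.22.

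Factors that cleave and polyadenylate transcripts did not pass as a group by camera in tumours against pro-B, and passed by fry (adjusted p = 0.045). Of 26, 6 rose and 2 fell (8 over the list alone, median 0.07, adjusted p = 0.314). Cpsf6, a subunit of the factor that favours distal poly(A) sites, rose by 1.23 ± 0.15 (2.35-fold, medians 5310 and 2180, adjusted p = 2.4e-07), the endonuclease Cpsf3 by 0.90 ± 0.21, Cpsf1 by 0.66 ± 0.12 and the poly(A)-binding Pabpc1 by 0.55 ± 0.14. With the mean of its probe sets Cpsf6, tumours vs pro-B, stood at 0.28 (adjusted p = 0.213). The poly(A) polymerase Papolg changed by -0.66 ± 0.20 and Cstf2t by -0.62 ± 0.22. Splicing factors were not passed by camera (9 of 29 rose, 2 fell, median 0.12, adjusted p = 0.113, and adjusted p = 0.0193 by fry), nor was the microRNA pathway (4 of 13 rose, 4 fell, adjusted p = 0.859). In the latter Drosha, which cuts primary microRNAs, rose by 1.04 ± 0.24 and Prkra changed by -2.43 ± 0.36. Genes of DNA replication (3 of 27 rose, 2 fell, adjusted p = 0.67), mitosis (0 of 24 rose, 4 fell, adjusted p = 0.557) and non-homologous end joining (2 of 10 rose, 3 fell, adjusted p = 0.595) were not passed. Nor were homologous recombination (5 of 16 rose, median 0.53, adjusted p = 0.0562) and hypoxia and glycolysis (9 of 18 rose, 3 fell, median 0.55, adjusted p = 0.0532). The same held for the neighbours of Myc (2 of 12 rose, 1 fell, adjusted p = 0.332, the noncoding Pvt1 2.96 ± 0.84) and of Mycn (2 of 9 rose, adjusted p = 0.407). Fry, which does not set a list against other genes, passed homologous recombination (adjusted p = 0.0421), hypoxia (adjusted p = 7.3e-04), the neighbours of Mycn (adjusted p = 0.0432), erythroid (adjusted p = 2.2e-04) and germinal centre genes (adjusted p = 0.00287). By camera, homologous recombination and hypoxia each reached adjusted p = 0.0263 after quantile normalization, and erythroid and germinal centre genes each adjusted p = 0.0394. Erythroid markers also passed with a common 75th percentile (adjusted p = 0.0474). Leaving out 1 array let homologous recombination pass without pro-B 2, LPC 1, LPC 2, APC 4 or APN 2 (adjusted p = 0.0456, 0.0448, 0.045, 0.0348 and 0.0495). Hypoxia genes passed without pro-B 2, LPC 2, APC 5, APC 9, APN 2, APN 3 or APN 5 (adjusted p = 0.0404, 0.045, 0.0411, 0.0483, 0.0495, 0.0422 and 0.0474), splicing factors without pro-B 2 (adjusted p = 0.042) and erythroid markers without LPC 1 or APN 2 (adjusted p = 0.0476 and 0.0495).

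Taken apart, LPC differed from pro-B in 4560 genes (2334 higher, 2226 lower), APC in 5153 (2565 higher, 2588 lower) and APN in 4602 (2275 higher, 2327 lower). Without pro-B 1 these counts were 2380, 2894 and 2568, and without pro-B 2 they were 2485, 2958 and 2633. Ribosome biogenesis genes rose in 34, 36 and 33 of 37 (medians 0.97, 1.14 and 0.86, adjusted p = 0.0237, adjusted p = 0.0129 and adjusted p = 0.0274 with an estimated correlation). Pro-B and pre-B cell genes fell in 15, 15 and 14 of 17 (medians -2.03, -2.58 and -2.38). Interferon genes passed in APC (13 of 18 fell, 14 over the list alone, median -1.87, adjusted p = 3.1e-05, and adjusted p = 0.351 with an estimated correlation). They passed in APN too (14 fell, 15 over the list alone, median -1.94, adjusted p = 1.7e-06, and adjusted p = 0.27 with an estimated correlation). In LPC they were not passed (4 fell, median -0.94, adjusted p = 0.0964), and the call was reached without LPC 1 (adjusted p = 0.0307) or LPC 2 (adjusted p = 0.0354). Stromal markers rose in 15, 15 and 14 of 15 (medians 4.88, 4.46 and 3.84, or 3.26, 3.14 and 2.56 with members at their bound). Genes active in salivary glands were among those named for single types: Mucl2 in LPC (at least 21.2-fold, adjusted p = 0.0423), and Smr3a (at least 22.7-fold), Bpifa2 (at least 77.1-fold) and Cst10 (at least 3.58-fold) in APN. Skeletal muscle genes scored 3.73 in APN 6, 2.45 in APN 3 and 2.08 in APC 11, and at most 0.45 on the other arrays. Mucl2 read 38327 in LPC 1 and 36691 in LPC 2, where the median of LPC was 468, and without both arrays Mucl2, LPC vs pro-B, was not called (adjusted p = 0.142). Without pro-B 1 none of the 4 was called: adjusted p = 0.276 for Mucl2, LPC vs pro-B, adjusted p = 0.0972 for Smr3a, APN vs pro-B, adjusted p = 0.0956 for Bpifa2, APN vs pro-B, and adjusted p = 0.0877 for Cst10, APN vs pro-B.

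Probe sets of 1 gene often changed unequally between tumours and pro-B cells. Hnrnpu encodes an RNA-binding protein of the nucleus, and 1 of its probe sets rose by 2.32 ± 0.16 (medians 2630 and 497) while a brighter one fell by 0.58 ± 0.20 (8440 and 12000, F test adjusted p = 2.0e-17). Unequal change was called for 872 of 6324 genes (13.8%), and in 164 genes probe sets changed in opposite directions. With signals below the median of their array raised to it, 706 of the 872 and 156 of the 164 were called again. The array medians of pro-B (65.4 to 66.3) lay below those of all tumour arrays. Raising thus puts a rise in tumours into dim probe sets, so the calls kept do not show that dim signals played no part. Others were the ubiquitin-conjugating Ube2d2a (2.29 ± 0.33 and -0.54 ± 0.12), the cohesin subunit Stag1 (1.30 ± 0.25 and -0.95 ± 0.16), and the phosphatase Mdp1 (2.28 ± 0.24 and -0.73 ± 0.15). In the last 4 the higher probe set lay below the array medians in pro-B, and its difference shrank once such signals were raised. These were Spata13, an exchange factor for small GTPases (medians 79.9 and 3.29, 0.74 when raised, beside -1.42 ± 0.25), Oaz2 (104 and 19, 0.77 when raised, beside -0.98 ± 0.20), the corepressor subunit Tbl1xr1 (111 and 18.1, 0.97 when raised, beside -1.37 ± 0.26) and Kansl1 (144 and 42.8, 1.13 when raised, beside -1.18). In 606 of the 872 genes (69.5%) the dimmest probe set was the relatively higher one in tumours, against 51.3% of all 6324. LPC, APC and APN taken apart gave 887, 768 and 722 genes. Without pro-B 1 the counts for all tumours, LPC, APC and APN were 354, 361, 322 and 308, and without pro-B 2 they were 374, 381, 338 and 328. Genes with opposite probe sets then numbered 38 and 39 for all tumours. No direction of 3'-UTR change was assigned, because the tables do not place the probe sets along the transcripts.

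Tumours differed from mature B cells in genes of dividing cells, in receptors of resting B cells and in stromal genes. Ttk, a kinase of the spindle checkpoint, rose by 3.45 ± 0.17 (10.9-fold, medians 1620 in 23 tumours and 129 in 4 mature B arrays, adjusted p = 3.6e-16). Cr2, the complement receptor of mature B cells, changed by -9.54 ± 0.60 (at least 134-fold lower, 18.8 and 11600, adjusted p = 9.6e-14), and Fcer2a, the low-affinity IgE receptor, by -8.54 ± 0.49 (at least 105-fold lower, 24.4 and 9290). Of 12927 genes 7464 changed, 3690 higher and 3774 lower, and 1933 and 1794 by at least 2-fold. Also high in tumours were Mnd1, a recombination factor (6.68 ± 0.29, at least 5.67-fold), and the matrix protein Sparc (7.15 ± 0.45, at least 23.6-fold). So were Pdgfrb (at least 4.87-fold), Sparcl1 and Rgs5 (6.39 ± 0.42). Low were Egr3 (-7.08 ± 0.57), the IgM Fc receptor Fcmr (134-fold) and Eps8l1 (at least 8.14-fold). A common 75th percentile moved the median of all genes by 0.14 log2 in this comparison and by 0.10 in APC against pro-B, and quantile normalization moved mature B against pro-B by -0.12. Relative to mature B, Myc in the tumours was not passed (1.00 ± 0.49, adjusted p = 0.0793), but it was with a common 75th percentile (1.14, adjusted p = 0.0423), with an offset before the log (1.04, adjusted p = 0.0486) and with array weights (0.94, adjusted p = 0.029). It was passed too without APN 3 (1.13, adjusted p = 0.031) or APN 4 (1.17, adjusted p = 0.0137). The tumour value of Myc averaged groups on both sides of mature B (median 1624): medians were 13259 in LPC, 14255 in APC and 252 in APN.

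All 24 mitosis genes rose over mature B (median 2.82, adjusted p = 6.1e-21, and adjusted p = 0.0446 with an estimated correlation). So did all 27 of DNA replication (median 1.96, adjusted p = 3.4e-18, and adjusted p = 0.0502 with an estimated correlation). Cdc6, which loads the replicative helicase, rose by 3.68 ± 0.16 (12.8-fold). All 37 genes of ribosome biogenesis rose (median 1.09, adjusted p = 0.0348 with an estimated correlation), and the spermidine synthase Srm did so by 2.56 ± 0.12 (5.88-fold). Of homologous recombination genes 15 of 16 rose (median 1.91, or 1.70 with 2 members at their bound, adjusted p = 2.0e-08, and adjusted p = 0.089 with an estimated correlation). Mature B cell genes fell in all 24 (median -2.68, adjusted p = 2.8e-13, and adjusted p = 0.0268 with an estimated correlation), and the homing receptor Cxcr5 stood at -5.92 ± 0.40. Pro-B and pre-B cell genes rose for 12 of 17 and fell for 2 (median 1.60, or 1.09 with 4 at their bound, adjusted p = 0.00347, and adjusted p = 0.206 with an estimated correlation). Rag1, which cuts antibody genes for rearrangement, rose by 2.91 ± 0.68 (7.54-fold). B lineage identity genes fell for 11 of 15 and rose for 1 (median -1.04, adjusted p = 6.2e-04, and adjusted p = 0.2 with an estimated correlation). Germinal centre genes fell for 8 of 11 (median -1.05, or -0.90 with 3 at their bound, adjusted p = 0.0165, and adjusted p = 0.2 with an estimated correlation, Bcl6 -4.17 ± 0.43). Splicing factors rose for 20 of 29 and fell for 2 (median 0.43, adjusted p = 6.2e-04, and adjusted p = 0.2 with an estimated correlation, Srsf2 0.98 ± 0.07).

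Interferon genes fell for 17 of 18 against mature B (median -2.35, adjusted p = 3.2e-05, and adjusted p = 0.263 with an estimated correlation, the antiviral Mx1 -3.34 ± 0.56). Hypoxia and glycolysis genes rose for 9 of 18 and fell for 2 (median 0.81, or 0.62 with 2 at their bound, adjusted p = 0.00845, and adjusted p = 0.2 with an estimated correlation). Ldha, the lactate dehydrogenase of glycolysis, rose by 1.69 ± 0.10. Apoptosis regulators fell for 8 of 17 and rose for 3 (12 over the list alone, median -0.20, adjusted p = 0.0404, and adjusted p = 0.089 with an estimated correlation), a call lost without LPC 1 (adjusted p = 0.0507). The survival gene Bcl2 stood at -3.13 ± 0.24 (8.74-fold). Immediate early genes fell for 12 of 21 and rose for 4 (median -0.92, adjusted p = 0.029, and adjusted p = 0.392 with an estimated correlation). That call was lost without mature B 1 (adjusted p = 0.0627) or mature B 2 (adjusted p = 0.0508). Among markers of other cells, stromal ones rose in all 15 (median 4.09, or 2.85 with 8 at their bound, adjusted p = 0.169 with an estimated correlation) and endothelial ones in 12 of 13 (median 2.19, or 0.91 with 10 at their bound, adjusted p = 0.089 with an estimated correlation). T cell markers fell in 11 of 15 (median -2.36, or -1.30 with 5 at their bound, adjusted p = 0.0268 with an estimated correlation) and NK and dendritic cell markers in 7 of 8 (median -3.58, or -3.01 with 1 at its bound, adjusted p = 0.089 with an estimated correlation).

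Cleavage and polyadenylation factors did not pass by camera against mature B, with members going both ways: 12 of 26 rose and 4 fell (16 over the list alone, median 0.27, adjusted p = 0.246). By fry they passed (adjusted p = 0.00216). Pabpc4, a poly(A)-binding protein, rose by 1.13 ± 0.10 and Nudt21, the partner of Cpsf6 in choosing distal sites, by 0.88 ± 0.09 (medians 8370 and 4400, adjusted p = 1.6e-09). With the mean of its probe sets Nudt21, tumours vs mature B, stood at 0.03 (adjusted p = 0.928). Papolg changed by -1.28 ± 0.14, Pcf11 by -0.89 ± 0.11, Cpsf7 by -0.87 ± 0.16 and Cstf2t by -0.81 ± 0.16. Unequal change was called for 650 of 6324 genes (10.3%), 133 with opposite probe sets. The dimmest probe set was relatively higher in tumours in 232 of them (35.7%), against 43.2% of all 6324. Without mature B 2 there were 85 genes with opposite probe sets and without mature B 4 there were 84.

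**Figure D3:**
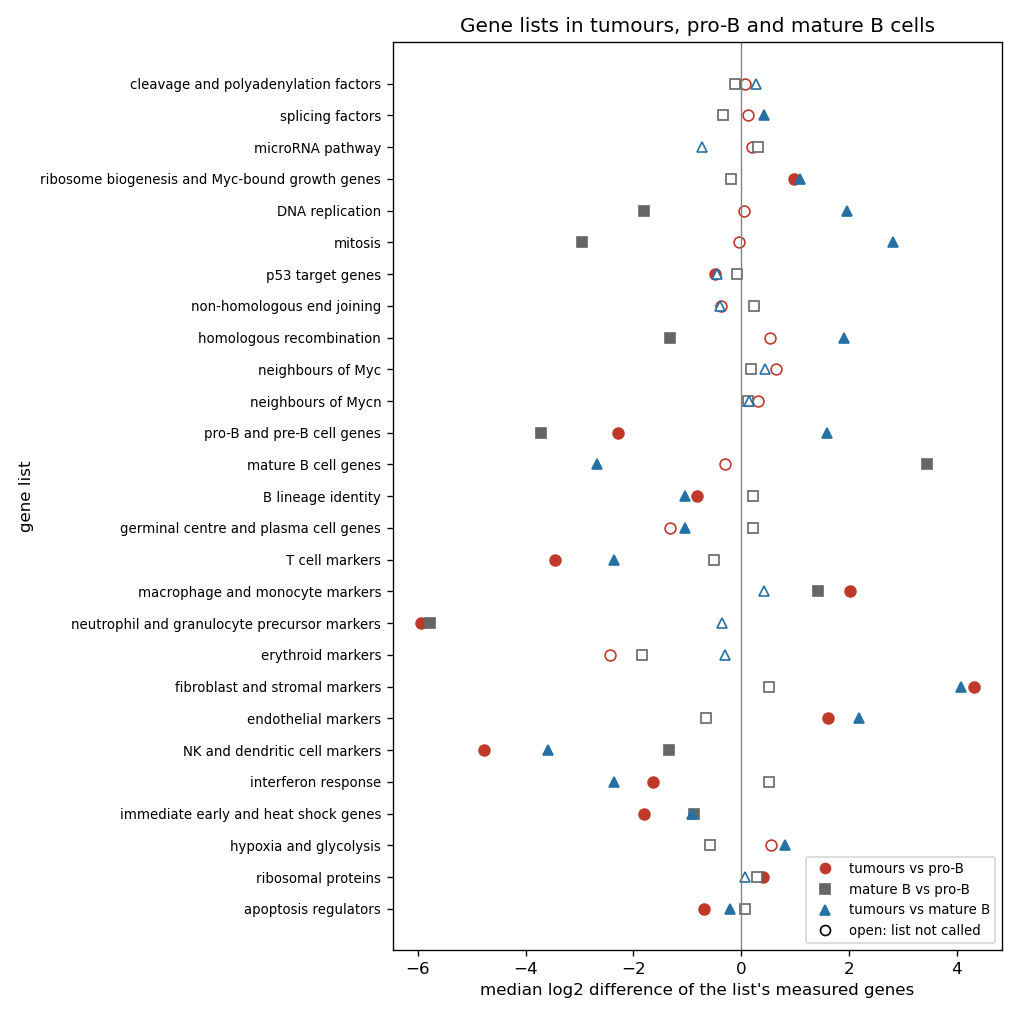
Median log2 difference of each gene list in tumours against pro-B, mature B against pro-B and tumours against mature B, with open symbols for lists not called by camera.

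Mature B and pro-B cells differed in the genes of the cell cycle, of early B cells and of mature B cells. Vpreb1, part of the pre-B cell receptor, was at least 177-fold lower in mature B (log2 difference -10.10, medians 15.2 in 4 mature B and 15800 in 2 pro-B arrays, adjusted p = 5.7e-06). Rag2, the partner of Rag1, changed by -8.07 ± 1.14 (at least 28.5-fold lower) and Igll1 by -7.75 ± 1.17 (medians 96.9 and 18700). Cr2 rose by 7.57 ± 0.96 (11600 and 62.1), Fcer2a by 5.92 ± 0.77 (60.6-fold), the bacterial lipoprotein sensor Tlr1 by 6.18 ± 0.66 (72.6-fold) and Pxdc1 by 6.22 ± 0.36. There were 4058 changed genes, 1958 higher and 2100 lower, and 1148 and 1306 by at least 2-fold. Without pro-B 1 the count was 2507 and without pro-B 2 it was 2164. All 24 mitosis genes fell (median -2.95, adjusted p = 0.00875 with an estimated correlation), as did 26 of 27 of DNA replication (median -1.80, adjusted p = 0.0177 with an estimated correlation). All 17 pro-B and pre-B cell genes fell (median -3.72, adjusted p = 0.00644 with an estimated correlation). Of homologous recombination genes 10 of 16 fell (median -1.32, or 2-fold lower with 2 at their bound, adjusted p = 4.5e-07, and adjusted p = 0.188 with an estimated correlation). Mature B cell genes rose for 21 of 24 (24 over the list alone, median 3.46, adjusted p = 0.00875 with an estimated correlation).

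Neutrophil markers were lower in mature B than in pro-B for 13 of 14 (median -5.77, or -4.83 with 5 at their bound, adjusted p = 0.0177 with an estimated correlation, Camp -7.40 ± 1.30). Macrophage markers rose for 10 of 18 and fell for 3 (median 1.43, or 0.96 with 2 at their bound, adjusted p = 0.00728, and adjusted p = 0.583 with an estimated correlation). NK and dendritic cell markers fell for 3 of 8 (median -1.34, adjusted p = 0.0455, and adjusted p = 0.542 with an estimated correlation). The call was lost under both scalings (-1.39, adjusted p = 0.0727, and -1.42, adjusted p = 0.0508) and without pro-B 1 (adjusted p = 0.0548), mature B 1 (adjusted p = 0.0546) or mature B 2 (adjusted p = 0.0733). Immediate early genes fell for 8 of 21 and rose for 1 (median -0.88, adjusted p = 0.035, and adjusted p = 0.583 with an estimated correlation, Fos -3.89 ± 0.96). This call was lost after quantile normalization (-0.91, adjusted p = 0.0541) and without pro-B 2 (adjusted p = 0.306), mature B 3 (adjusted p = 0.0643) or mature B 4 (adjusted p = 0.0577). Cleavage and polyadenylation factors were not passed (5 of 26 rose, 6 fell, median -0.11, adjusted p = 0.871). Among them Cpsf6 stood at 1.09 ± 0.18 (-0.02, adjusted p = 0.954 with the mean of its probe sets), the termination factor Pcf11 at 1.06 ± 0.17, Nudt21 at -0.80 ± 0.14 and Pabpc4 at -0.67 ± 0.15. With the mean of its probe sets Nudt21, mature B vs pro-B, stood at -0.29 (adjusted p = 0.626). Unequal change was called for 866 of 6324 genes (13.7%), 144 with opposite probe sets. The dimmest probe set was relatively higher in mature B in 663 (76.6%), against 55.2% of all 6324. Without pro-B 1 these 866 were 463 (60 opposite) and without pro-B 2 they were 427 (52 opposite).

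LPC and APC, which share amplified Myc, differed in few genes. Gdpd3, a lysophospholipase, changed by -4.07 ± 0.53 (medians 58 in 6 LPC and 1000 in 11 APC arrays, adjusted p = 2.7e-04), and Rps4l, a paralogue of a ribosomal protein gene, rose by 4.30 ± 0.63 (363 and 12, adjusted p = 8.8e-04). Interferon response genes, which cells switch on after sensing viruses, had a median 1.44 higher in LPC (0.76 without LPC 1 and LPC 2) with 1 of 18 called. As a list they passed at the preset correlation (adjusted p = 6.0e-15) and not with an estimated one (adjusted p = 0.253). Of 12927 genes, 68 changed, 32 higher and 36 lower in LPC, and 15 and 12 by at least 2-fold. Others were Prxl2c (1.61 ± 0.30, its other probe set -0.06 ± 0.24), Ypel2 (2.83-fold), the arachidonate-oxidizing Cyp2c23 (-3.78 ± 0.59, at least 2.8-fold) and Zfp286 (-2.27 ± 0.40, at least 1.19-fold). Pik3ap1, an adaptor of B cell receptor signalling, changed by -1.91 ± 0.37 (285 and 1210, its other probe set 0.27 ± 0.30) and Bloc1s2 by -1.05 ± 0.19. The antiviral Rsad2 rose by 2.17 ± 0.46 (4.49-fold, 923 and 137, adjusted p = 0.0245), a call lost without LPC 1 (adjusted p = 0.103), LPC 2 (adjusted p = 0.0874) or LPC 3 (adjusted p = 0.0764). The 68 became 33 without LPC 1, 21 without LPC 2, 41 without LPC 3, 45 without LPC 4, 323 without LPC 5, 145 without LPC 6, 45 without APC 3 and 42 without APC 7.

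Of the lists in LPC against APC, interferon genes had a median of 1.44, or 1.40 with 1 member at its bound (1 of 18 rose, 17 over the list alone, adjusted p = 6.0e-15, and adjusted p = 0.253 with an estimated correlation). Scores of this list were 2.17, 1.84, 0.95, 0.47, -0.73 and -0.32 in LPC 1 to LPC 6, and -1.77 to 0.12 in APC. Without LPC 1 and LPC 2 the median was 0.76 (adjusted p = 1.1e-06). Neutrophil markers had a median of 1.00, or 0.58 with 5 at their bound (0 of 14 passed by limma, 3 over the list alone, adjusted p = 0.00161, and adjusted p = 0.253 with an estimated correlation). Ribosome biogenesis genes were slightly lower in LPC (median -0.21, 1 of 37 fell, 6 over the list alone, adjusted p = 1.2e-08, and adjusted p = 0.253 with an estimated correlation), a call lost without LPC 1 and LPC 2 (-0.10, adjusted p = 0.125). Cleavage and polyadenylation factors were lower in LPC by a median of -0.14 (1 of 26 fell, 3 over the list alone, adjusted p = 2.9e-04, and adjusted p = 0.253 with an estimated correlation), a call lost without LPC 1 and LPC 2 (-0.07, adjusted p = 0.338). Ints11, an endonuclease related to Cpsf3, changed by -0.43 ± 0.08 (medians 1350 and 1830, adjusted p = 0.00754). The lists of DNA replication (-0.18, adjusted p = 0.00303), splicing (-0.06, adjusted p = 0.0122), mitosis (-0.13, adjusted p = 0.0122), endothelial (0.40, adjusted p = 0.0192) and macrophage genes (-0.30, adjusted p = 0.0294) passed with no member called by limma. With an estimated correlation they had adjusted p = 0.856, adjusted p = 0.651, adjusted p = 0.856, adjusted p = 0.472 and adjusted p = 0.856, and by fry adjusted p = 0.108 or more. Each of these 5 calls was lost after quantile normalization (-0.14, adjusted p = 0.0682, -0.05, adjusted p = 0.357, -0.09, adjusted p = 0.201, 0.21, adjusted p = 0.111, and -0.25, adjusted p = 0.163). Single arrays ended them too: DNA replication was not passed without LPC 1 (adjusted p = 0.172), splicing without LPC 1 or LPC 2 (adjusted p = 0.172 and 0.0894), mitosis without LPC 1 or LPC 4 (adjusted p = 0.404 and 0.206) and endothelial genes without LPC 1 or APC 4 (adjusted p = 0.102 and 0.0557). Macrophage genes were not passed without LPC 3, LPC 5, LPC 6, APC 1, APC 2 or APC 4 (adjusted p = 0.133, 0.329, 0.188, 0.0906, 0.0511 and 0.158).

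Unequal change in LPC against APC was called for 24 genes and opposite change for none (limma diffSplice, 515 at an unadjusted p under 0.05). The kinase gene Map3k7 had a probe set up by 1.03 ± 0.16 (675 and 312) beside another at -0.02 ± 0.12 (342 and 326, F test adjusted p = 2.8e-04). With signals below the array median raised to it 27 genes were called, 19 of them among the 24. The folate enzyme Shmt1 had a probe set at -0.93 ± 0.18 (939 and 1910) and the sulfhydryl oxidase Gfer one at -1.05 ± 0.17 (318 and 712). Elavl1, an RNA-binding protein of 3'-UTRs, had a dim probe set with medians of 24.4 and 220, at -0.99 (adjusted p = 0.0864) with such signals raised, beside a bright one at 0.01 ± 0.08. These genes were picked after the values had been seen. The 24 were 263 with array weights, 285 with the replicate block, 115 with the Gapdh covariate, 253 without LPC 1 and LPC 2, 13 with only the groups compared and 11 with the filter at the 75th percentile. With the Gapdh covariate or the block 2 genes had opposite probe sets. The 24 became 42 without LPC 2, 13 without LPC 4, 51 without APC 9 and 40 without APC 10, and 1 gene with opposite probe sets appeared without LPC 5.

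APC and APN differed in the oncogenes and in some of the genes next to them. Myc was 6.02 ± 0.45 higher in APC (64.8-fold, 11 and 6 arrays, adjusted p = 1.3e-09) and Mycn -6.17 ± 1.17 (above the array median on 9 of the 11 APC arrays, adjusted p = 0.0083). Pvt1, a noncoding gene beside Myc, rose by 3.05 ± 0.57 (8.26-fold, medians 1570 and 201, adjusted p = 0.00801). St6galnac4, a sialyltransferase, rose by 1.44 ± 0.14 (2.71-fold, 1200 and 427, adjusted p = 4.2e-07). Of 12927 genes, 101 changed, 63 higher and 38 lower in APC, and 18 and 7 by at least 2-fold. With a common 75th percentile the split was 74 and 17. Others were Nbeal2 (1.18 ± 0.15), Mcrip2 (1.09 ± 0.20), the ribosomal Rps6 (1.01 ± 0.17, 1920 and 1010) and the secreted Egfl6 (-2.20 ± 0.44, 262 and 1130). The 101 became 159 without APC 5, 60 without APC 7, 43 without APN 3, 34 without APN 5 and 63 without APN 6.

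Neighbours of Myc were higher in APC than in APN (median 0.59, 1 of 12 rose, 2 over the list alone, adjusted p = 2.0e-05, and adjusted p = 0.0497 with an estimated correlation). Neighbours of Mycn were lower (median -0.54, 1 of 9 fell, 4 over the list alone, adjusted p = 6.6e-05, and adjusted p = 0.0403 with an estimated correlation). Of the 30 measured genes nearest Myc on chromosome 15, 28 were higher in APC, and of the 30 nearest Mycn on chromosome 12, 17 were lower. Macrophage markers were higher in APC (median 0.64, 1 of 18 rose, 10 over the list alone, adjusted p = 3.0e-07, and adjusted p = 0.354 with an estimated correlation). So were stromal markers (0.64, adjusted p = 8.5e-04), immediate early (0.48, or 0.46 with 2 at their bound, adjusted p = 3.5e-04) and hypoxia genes (0.22, or 0.17 with 1 at its bound, adjusted p = 0.00717, but adjusted p = 0.0538 without APN 3). Higher too were ribosome biogenesis (0.13, 1 rose, 7 over the list alone, adjusted p = 7.9e-06) and ribosomal protein genes (0.16, adjusted p = 1.4e-07, after quantile normalization 0.02, adjusted p = 0.071). DNA replication (-0.20, adjusted p = 4.6e-05) and homologous recombination (-0.25, adjusted p = 3.2e-04) were lower. With an estimated correlation the lists other than the neighbours had adjusted p = 0.354 or more, and by fry adjusted p = 0.0673 or more. Cleavage and polyadenylation factors were not passed (0 of 26 by limma, median 0.04, adjusted p = 0.622). Unequal change was called for 3 genes, Isoc1 (-1.08 ± 0.24, 972 and 2290), Mycn and Ap1g1, the last not called with signals below the array median raised to it, and opposite change for none (181 unequal at an unadjusted p under 0.05).

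**Figure D4:**
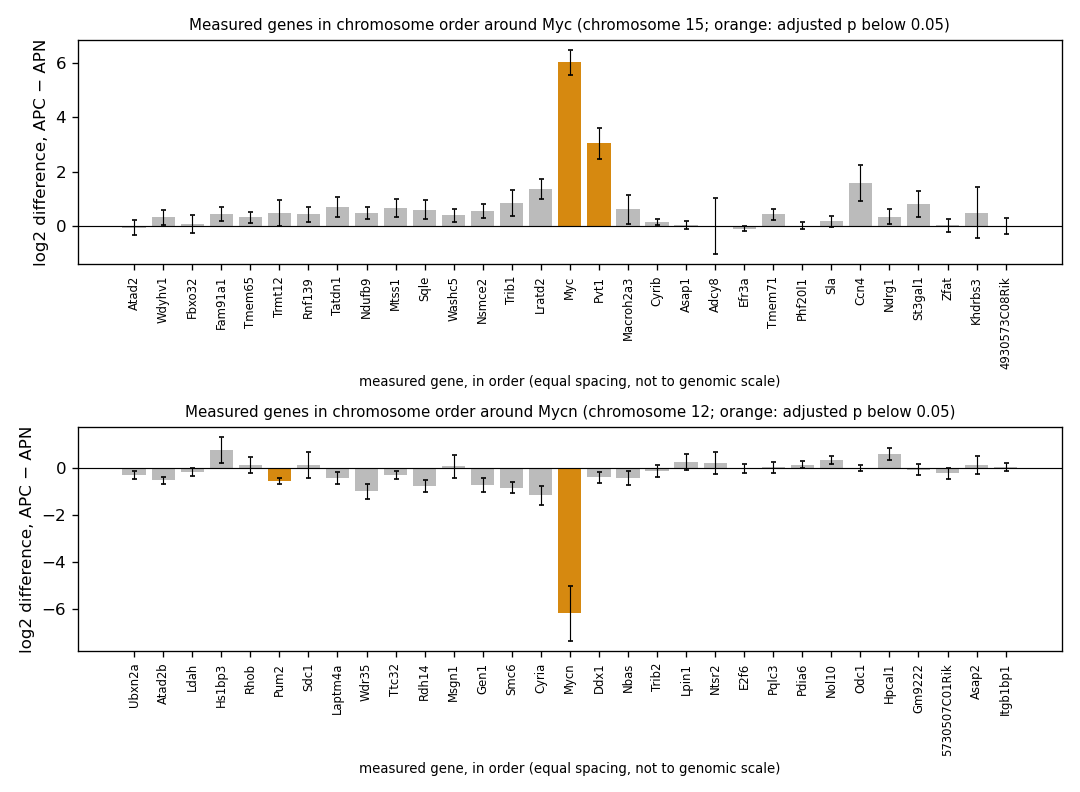
Log2 differences from APN of the measured genes in order along the chromosomes round Myc and Mycn.

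LPC and APN, which differ in both the deleted repair gene and the oncogene, differed in 459 genes, and in 110 without LPC 1 and LPC 2, where APC and APN differed in 101. Myc was 5.94 ± 0.51 higher in LPC (61.4-fold, 6 and 6 arrays, adjusted p = 4.0e-08), Mycn -8.96 ± 1.33 (above the array median on 2 of the 6 LPC arrays, adjusted p = 5.7e-04) and Pvt1 3.42 ± 0.65 higher (10.7-fold, medians 1820 and 201, adjusted p = 0.00615). Rps6, a protein of the small ribosomal subunit, rose by 1.63 ± 0.19 (3.09-fold, 3010 and 1010, adjusted p = 1.5e-05). The 459 of 12927 genes were 235 higher and 224 lower in LPC, and 151 and 56 by at least 2-fold. Others were Rps4l (4.87 ± 0.72, at least 3.93-fold), the fatty acid transporter Cpt1a (1.54 ± 0.31), the interferon-inducible Slfn8 (1.54 ± 0.26) and Cav2 (1.54 ± 0.32). Lower were Efcab7 (-1.32 ± 0.17), Syce2 (-1.16 ± 0.24), Cyp2c23 (-3.85 ± 0.67, at least 2.95-fold) and Zfp286 (-3.02 ± 0.46, at least 1.99-fold). The 459 became 141 without LPC 1, 167 without LPC 2, 269 without LPC 3, 885 without LPC 5, 822 without LPC 6, 203 without APN 1, 274 without APN 3, 228 without APN 4 and 247 without APN 5.

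Interferon genes were higher in LPC than in APN (median 1.89, or 1.76 with 1 at its bound, 10 of 18 rose, 15 over the list alone, adjusted p = 6.0e-13, and adjusted p = 0.154 with an estimated correlation). The chemokine Cxcl10 rose by 2.70 ± 0.54 (adjusted p = 0.00753). Without LPC 1 and LPC 2 the median over APN was 1.26 (adjusted p = 1.4e-07). Neutrophil markers had a median of 1.38, or 0.22 with 7 at their bound (2 of 14 rose, 6 over the list alone, adjusted p = 1.2e-04, and adjusted p = 0.154 with an estimated correlation, S100a8 2.84 ± 0.61). Neighbours of Myc were higher (median 1.01, or 0.94 with 1 at its bound, 1 of 12 rose, 7 over the list alone, adjusted p = 1.2e-04, and adjusted p = 0.154 with an estimated correlation). Those of Mycn were lower (-0.57, 1 of 9 fell, adjusted p = 0.00522, and adjusted p = 0.154 with an estimated correlation). DNA replication genes fell for 4 of 27 (11 over the list alone, median -0.38, adjusted p = 7.4e-08, and adjusted p = 0.261 with an estimated correlation, the helicase subunit Gins2 -0.75 ± 0.12). Immediate early (0.99, or 0.85 with 2 at their bound, adjusted p = 1.2e-04) and ribosomal protein genes (0.18, adjusted p = 2.9e-06, after quantile normalization 0.01, adjusted p = 0.102) were higher and homologous recombination genes lower (-0.30, or -0.27 with 1 at its bound, adjusted p = 5.1e-04). Without LPC 1 and LPC 2 immediate early genes stood at 0.41 (adjusted p = 0.00158) and DNA replication at -0.19 (adjusted p = 0.00364), and homologous recombination was not passed (-0.13, adjusted p = 0.121). Higher too were stromal (0.65, adjusted p = 0.00106), endothelial (0.49, adjusted p = 0.00409), hypoxia (0.27, adjusted p = 0.0146) and macrophage genes (0.30, adjusted p = 0.046). Without LPC 1 and LPC 2 these 4 lists were not passed (0.38, adjusted p = 0.0877, 0.22, adjusted p = 0.0544, 0.24, adjusted p = 0.055, and 0.12, adjusted p = 0.375). With an estimated correlation no list passed in LPC against APN (lowest adjusted p = 0.154), and fry did not pass homologous recombination, stromal or macrophage genes (adjusted p = 0.0628, 0.165 and 0.317). Hypoxia genes were not passed without LPC 1 alone (adjusted p = 0.0531), nor macrophage genes without LPC 1, LPC 2, LPC 4, APN 3, APN 4 or APN 5 (adjusted p = 0.086, 0.121, 0.353, 0.113, 0.165 and 0.0528).

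Cleavage and polyadenylation factors were lower in LPC than in APN by a median of -0.10 (2 of 26 fell, over the list alone 1 rose and 7 fell, adjusted p = 0.0177, adjusted p = 0.333 with an estimated correlation, and adjusted p = 0.0628 by fry). Cstf1, a subunit of the cleavage stimulation factor, changed by -0.55 ± 0.11 (medians 1030 and 1550, adjusted p = 0.00727) and Ints11 by -0.37 ± 0.09 (1350 and 1750, adjusted p = 0.0225), the latter not called without LPC 1, LPC 2 or APN 1 (adjusted p = 0.0664, 0.0506 and 0.0574). The list call was lost after quantile normalization (-0.12, adjusted p = 0.0607), without LPC 1 (adjusted p = 0.169), without LPC 2 (adjusted p = 0.0606) and without both (-0.07, adjusted p = 0.628). Splicing factors had a median of -0.05 (adjusted p = 0.0374, adjusted p = 0.48 with an estimated correlation, adjusted p = 0.177 by fry, and adjusted p = 0.779 without LPC 1 and LPC 2). They were not passed without LPC 1, LPC 2, LPC 4, APN 1, APN 4 or APN 6 either (adjusted p = 0.201, 0.146, 0.0836, 0.125, 0.116 and 0.0573). Unequal change was called for 23 genes (limma diffSplice, 382 at an unadjusted p under 0.05), 58 with array weights, 59 without LPC 1 and LPC 2 and 9 with the filter at the 75th percentile. Snapc3, a subunit of the complex that starts small nuclear RNA transcription, was the 1 gene with opposite probe sets. In it 1 probe set stood at -0.80 ± 0.16, another at -0.77 ± 0.16 and 1 rose by 1.12 ± 0.25 (361 and 143, F test adjusted p = 1.4e-08). There were 2 such genes without LPC 5, without APN 1 or without APN 6. With signals below the array median raised to it 34 genes were called, 16 of them among the 23.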

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

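The tests of salivary gland genes in 2 of the LPC arrays against tissue next to the node and against genotype, and of unnamed probe sets against scaling or signal level, the tumours and handling, were chosen only after the result had been seen.

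In 99 checks of a group for 1 value far from the rest (Dixon's test), 8 values stood out, where about 1 in 20 checks, 4.95 in all, is expected by chance. Of the list scores, the microRNA pathway read 0.13 in APN 2 against -0.09 to -0.02 in the other APN arrays, the neighbours of Myc -0.26 in mature B 2 against -0.41 to -0.40, and the neighbours of Mycn -0.17 in LPC 3 against -0.01 to 0.04. Mature B cell genes scored 3.04 in mature B 3 against 2.90 to 2.91, and 0.53 in LPC 4 against -0.93 to -0.42. Stromal markers scored -1.81 in mature B 2 against -4.21 to -4.01 in the other mature B arrays. The Lig4 signal of APN 1 was 384 against 746 to 1002. The median correlation of mature B 2 with its group, taken over the tested genes and not over all probe sets, was 0.95 against 0.96. Each is 1 array of a group, and none was left out for it.

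Genes of the salivary glands, which lie next to the cervical nodes, were high in LPC 1 and LPC 2, with scores of 4.56 and 4.29 where the next tumour, APC 10, had 1.89. Of 13 salivary markers that had not been looked at before, 10 had LPC 1 and LPC 2 above all 21 other tumours, as had 10 of 17 that had been seen, against 0 of 8 and 0 of 7 skeletal muscle markers. Muscle genes stood apart on other arrays, with scores of 3.73 in APN 6, 2.45 in APN 3 and 2.08 in APC 11, where no other array passed 0.45. Pip, a secreted salivary protein, read 36722 and 35708 against a median of 3368 in the other tumours, and Smgc 14361 and 12561 against 32.9. The genotype explained it poorly, since 2 of the 6 LPC arrays lay above the highest APC or APN score, and scaling did not remove it, since the gap to the next tumour was 2.40 log2 as deposited and 2.37 after quantile normalization. Gland tissue taken along with the node is a candidate explanation, and these values may reflect it in LPC 1 and LPC 2. Some salivary genes were as high elsewhere: among the 21 other tumours the highest signal was 39505 for Mucl2, 35793 for Bpifa2 and 34593 for Dcpp1. Leaving out LPC 1 and LPC 2 therefore need not remove all salivary signal. The labels give no site per sample.

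Probe sets without a single gene name were set aside as genes, yet 2390 of 4912 differed between tumours and pro-B and 2249 between mature B and pro-B, and most of them were lower in pro-B. The share higher in tumours was 85.2%, against 53.5% of named probe sets of the same signal level. It was 79.6% after quantile normalization and 83.5% with the Gapdh covariate, so neither scaling nor the 3'-to-5' measure removed it, and it was 87.2% in mature B against pro-B, so the tumours were not needed for it. Handling of the sorted pro-B cells cannot be told apart from a property of these cells with 2 pro-B arrays, and either may be the cause. Another set of pro-B arrays, prepared apart, would decide.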

How the results depend on the processing

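The Xist covariate, leaving out LPC 1 and LPC 2 together and raising signals below the array median to it were chosen only after the result had been seen. Xist was uneven between the groups, at least 1500 on 5 of 6 APN and 3 of 11 APC arrays. With the Xist covariate 63 of 920 values of named genes lost their call and 0 reversed.

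Counts of changed genes moved over 1.5 times under these settings. Tumours against pro-B gave 8088 with array weights, LPC against pro-B 2979 at an adjusted p under 0.01, APC against pro-B 7872 with weights and APN against pro-B 7046 with weights. Mature B against pro-B gave 7028 with only the groups compared, 7356 with weights and 2633 at 0.01. LPC against APC gave 9 with only the groups compared, 117 with the Gapdh covariate, 16 at 0.01 and 16 without LPC 1 and LPC 2. APC against APN gave 57 without the trend, 33 with only the groups compared, 175 with Gapdh and 20 at 0.01. LPC against APN gave 291 without the filter, 61 with only the groups compared, 258 with weights, 57 at 0.01 and 110 without LPC 1 and LPC 2. Tested 1 by 1, 9251, 8254, 9061, 8117, 13190, 7479, 108, 134 and 583 of 24302 probe sets changed in the order of the report, which are counts of probe sets and not of genes. The replicate block gave 4942, 4462, 4729, 4346, 7255, 3994, 61, 62 and 490 in the order of the report. With a common 75th percentile LPC against APC split into 21 higher and 50 lower, where it had been 32 and 36. The numbers do not pair the samples: 38 pairs of arrays with a shared number had a median correlation of -0.00 (-0.23 to 0.45), and 4 of 29 arrays went best with their own number.

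Unequal probe sets moved as follows. With the filter at the 75th percentile the first 4 comparisons gave 335, 345, 312 and 286 and with weights 1635, 1739, 1468 and 1369. Tumours against mature B gave 172 with that filter, 1037 with weights, 986 with Gapdh and 405 without the _s, _x and _a kinds; mature B against pro-B 334 with that filter, 1522 with only the groups compared, 1829 with weights and 1318 with Gapdh. LPC against APC gave 11 with that filter, 13 with only the groups compared, 263 with weights, 115 with Gapdh, 285 with the replicate block, 14 without the _s, _x and _a kinds and 253 without LPC 1 and LPC 2. APC against APN gave 1 with that filter, 5 with Gapdh and 1 with the Xist covariate, and LPC against APN 9 with that filter, 58 with weights and 59 without LPC 1 and LPC 2. With signals below the array median raised to it the counts were 1131, 1228, 1044, 995, 846, 1160, 27, 4 and 34, of which 706, 728, 613, 576, 466, 717, 19, 2 and 16 had been called before. Opposite probe sets then numbered 340, 364, 142, 127, 116, 243, 0, 0 and 2, of which 156, 140, 116, 96, 109, 130, 0, 0 and 1 had been called before. Raising carries the differences between array medians into dim probe sets, so calls that it adds say little, and calls that it keeps are not free of this.

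Leaving out 1 array at a time gave these lowest and highest counts of changed genes: 2754 and 5282 for tumours against pro-B, 2380 and 4557 for LPC, 2894 and 5208 for APC and 2568 and 4571 for APN against pro-B, 6751 and 7518 for tumours against mature B, 2164 and 3687 for mature B against pro-B, 21 and 323 for LPC against APC, 34 and 159 for APC against APN and 141 and 885 for LPC against APN. The same range for unequal probe sets was 354 to 909, 361 to 953, 322 to 780, 308 to 731, 475 to 686, 427 to 804, 13 to 51, 2 to 3 and 17 to 31. For lists it was 14 to 17, 14 to 15, 14 to 17, 13 to 17, 16 to 17, 8 to 9, 5 to 10, 9 to 11 and 10 to 16.

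Lists passed with an estimated correlation numbered 5, 5, 5, 5, 4, 5, 0, 2 and 0 in the same order. Fry passed 15 for mature B against pro-B, 5 for LPC against APC and 2 for APC against APN. LPC against APC had 4 after quantile normalization and 3 without LPC 1 and LPC 2. LPC against APN had 7 without LPC 1 and LPC 2. No list reversed under any setting run.

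Single genes reversed in these cases. With the mean of a gene's probe sets Aurka was 1.18 in tumours, 0.73 in LPC, 1.28 in APC and 1.54 in APN against pro-B, Tpx2 0.00 in tumours and Cyrib 0.02 in APN against pro-B, Bak1 -0.16 in tumours against mature B, and Cpsf6 -0.02, Ptbp1 0.02, Tarbp2 0.04 and Rps3 -0.25 in mature B against pro-B. Without the filter Cd247 was 0.64 in tumours against mature B and Cacna2d1 0.98 in mature B against pro-B. With Gapdh Bak1 was -0.14. With only the groups compared Zap70 was 0.53 in mature B against pro-B and 0.09 in LPC against APN.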

Other observations

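The tests of neighbouring genes against inherited segments and against gene families, and of the run of genes on chromosome 12, were chosen only after the result had been seen.

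Genes that differed between the tumour types lay next to each other more often than in shuffled gene orders. Between LPC and APC, 22 of 68 had another within 10 measured genes on either side, where 10000 shuffled orders gave a median of 6 (0 to 14; permutation p = 2.0e-04). For APC against APN the number was 35 of 101, against 14 (6 to 24; permutation p = 2.0e-04), and for LPC against APN 260 of 458, against 234 (210 to 258; permutation p = 0.0195).

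Segments of the strain in which an allele was targeted can stay with it through backcrossing, and such segments may account for a part of this. Of the 22 genes, Fam107b and Nudt5 lay near Dclre1c, and most of the others lay on chromosomes 9, 11, 13, 17 and 19. The p53 locus, also disrupted in all these tumours, was not tested, so genes near it were not counted as near a targeted locus. The 76 measured genes nearest Lig4 and Dclre1c held 3 of the calls between LPC and APC where 0.385 were expected (one-sided Fisher exact p = 0.00749). These were Zfp958 near Lig4, and Fam107b and Nudt5 near Dclre1c. Zfp958 had no called neighbour, and its call was lost without LPC 2 (adjusted p = 0.0675). Fisher's test takes genes as independent, but calls lay together here, and Fam107b and Nudt5 were both among the 22 with a called neighbour. Its p-value is therefore too small and does not decide for inherited segments. Families of related genes that lie together are a second candidate: without the interferon-inducible and zinc finger families 12 of 59 calls had a called neighbour, which is exactly the upper end of the shuffled range (median 4, 0 to 12; permutation p = 0.0284), and the families were picked with the genes in view. With the interferon score as a covariate only 4 calls were left, 0 of them with a called neighbour, so that test says nothing. Genotypes along these chromosomes would separate the 2 candidates.

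On chromosome 12, away from Mycn, a run of 15 genes from Clba1 to Ighg3 was lower in LPC than in APN by a mean of -0.90, with 14 of the 15 lower, but this did not pass against the widest runs in 1000 shuffled orders (permutation p = 0.164). The overlapping run from Pld4 to Tmem121 was lower in APC than in APN by -0.83 (14 of 15 lower; permutation p = 1.0e-03, the smallest that 1000 shuffles can give). Tedc1 and Pacs2, a sorting protein, lay in it (Pacs2 -1.79 in LPC against APN). An extra copy of this segment in some APN tumours is a hypothesis that may be worth testing by copy number, which was not measured; the run scores of the APN arrays went from 1.33 (APN 2) to -0.25 (APN 4) and overlapped those of APC, where APC 2 had 0.78 and APC 5 0.42. Runs away from the oncogenes passed the same test elsewhere too. In LPC against APC these lay on chromosome 16 from Sh3bgr (0.89, permutation p = 0.011) and on chromosome 6 from Cav2 (0.85, permutation p = 0.026). Another was on chromosome 19 from Ms4a7 in APC against APN (0.60, permutation p = 0.037). In LPC against APN a run on chromosome 11 from Slfn2 passed (1.17, permutation p = 1.0e-03). Related genes that lie together were among their members: Mx1 and Mx2 on chromosome 16, Ms4a genes on chromosome 19, and Slfn and Ccl genes on chromosome 11. Shuffled orders do not allow for this, so these runs say nothing about copy number.

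The higher interferon genes of LPC were carried most by LPC 1 and LPC 2, the arrays with high salivary and stromal scores (stromal 2.52 and 1.83). Without them the medians over APC and APN were 0.76 and 1.26. Of the 4 arrays left LPC 3 and LPC 4 had the highest interferon scores (0.95 and 0.47). Among the LPC arrays, LPC 3 came next in salivary score after LPC 1 and LPC 2. However, APC 10 (1.89) and APC 1 lay above LPC 3 in salivary score. No APC array reached the interferon score of LPC 3 or LPC 4. The salivary score alone therefore does not account for the interferon scores of LPC 3 and LPC 4. LPC 5 and LPC 6, with interferon scores of -0.73 and -0.32, lay within the range of APC. Tissue next to the node could explain part of the difference, and whether it explains all of it is left open.

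Markers of granulocytes, NK and dendritic cells were high in the pro-B arrays although B220+ CD43+ IgM- cells had been sorted. Some NK and plasmacytoid dendritic cells carry B220 and CD43, which such a sort would not remove, and they may have added to the pro-B samples. The gate would remove most granulocytes, whose Camp and S100a9 were nonetheless at 5450 and 17800. Both pro-B arrays showed it: the median of the list of NK and dendritic cell markers, tumours vs pro-B, was -4.66 without pro-B 1 and -4.90 without pro-B 2, and the scores of the pro-B arrays were 4.15 and 3.98 against 2.23 to 2.61 in mature B. Part of the fall in the tumours would then be a property of the reference, which 2 pro-B arrays leave open.

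Random splits of the arrays asked how often another grouping gave as many calls. The real grouping is itself counted among the splits as large. With 100 splits a low count makes chance less likely but cannot exclude it. For tumours against mature B few splits gave as many changed genes (7464, highest other 161), unequal probe sets (650, highest other 51) or lists (17, highest other 17). These were 1, 1 and 2 of 100 splits, and for lists another split gave the same number. For LPC against APC no other split gave as many changed genes (68, highest other 41, 1 of 100) or unequal probe sets (24, highest other 18, 1 of 100). Many did for lists (9, highest other 13, 25 of 100). For APC against APN few splits gave as many changed genes (101, 2 of 100), although 1 other split reached 375. More did for unequal probe sets (3, highest other 737, 17 of 100) and lists (10, highest other 13, 10 of 100). For LPC against APN few splits gave as many changed genes (459, 2 of 100), although another split reached 545. More did for unequal probe sets (23, highest other 171, 6 of 100) and lists (14, highest other 17, 14 of 100). Splits with several times the real number, 375 against 101, 737 against 3 and 171 against 23, may point to a structure of the samples beside the tumour types, but what those splits share was not tested.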
